A study of Homo sapiens with 16 samples.

How the data were processed

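Total RNA from 3 human acute myeloid leukemia cell lines, MV411, THP1 and NOMO1, was hybridized to Affymetrix Human Genome U133 Plus 2.0 arrays, per the labels' protocols. The arrays carry 1 colour (a biotin label). The 16 arrays fall into 8 groups of 2, described per the labels as biological duplicates. p-values therefore measure the spread between these duplicates, and the labels do not say how the duplicates were grown.

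The deposited table holds log2 expression values, 1 column per array, with no pooling of arrays. That the scale is log2 was read from the range of the deposited values. The summarization and normalization methods and the genome build are not given in the sources used here. limma is named, with no version, per the submitters' processing notes. The lowest value of the deposited table, 2.17 on the log2 scale, is repeated on all arrays and acts as a floor. Between 40.0% and 41.6% of the deposited log2 values of an array lay at that floor. A difference from a group whose 2 arrays lay within 0.01 of the floor is a lower bound and is written as "at least". Above the floor, 2745 genes had at least 1 group whose 2 arrays held the same value to within 0.000001. Of the 8713 such groups over all genes, 4830 lay more than 0.01 above the lowest value of the gene, so the repeated values are not all lower limits, and their source is not known. A difference from such a group is not exact. A change hidden below the floor was not detectable at this signal level. The medians of the arrays lay between 2.45 and 2.63 and their 75th percentiles between 7.89 and 8.10. The deposited values were used without further normalization.

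The table has 54675 probe sets, of which 62 Affymetrix control probe sets were left out of the tests. Of the 54613 kept, 41091 had 1 gene symbol in the platform annotation, 1801 had several and 11721 had none. Symbols were looked up through their Entrez identifiers in the RefSeq gene table of GRCh38.p14, used for names alone, where 41037 probe sets matched, 54 did not and 0 symbols changed. A gene was represented by its probe set with the highest mean over the 16 arrays, which gave 19775 genes. Of these, 10523 had more than 1 probe set, and 4294 were at the floor on all 16 arrays. No position in the genome is given, because no build is named.

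Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) on the log2 values, with all 8 groups in 1 fit and 8 residual degrees of freedom. The prior degrees of freedom were 0.36, so the spread of each gene was moderated little. A group with both arrays at the floor has no spread and lowers the estimate that all groups share. Standard errors and p-values of genes at the floor in the other lines, such as DIRAS3 in THP1, can therefore be too small. A group whose 2 arrays lie far apart raises that estimate, so standard errors in the other groups can also be too large. All probe sets entered the fit, and p-values were adjusted by the Benjamini-Hochberg method over the 19775 genes within each comparison. A gene was called changed at an adjusted p below 0.05, and a change of 1 on the log2 scale is 2-fold. Differences are given with the standard error of the fit and group levels with the SD of 2 arrays. The comparisons were each compound against DMSO in its own line, GSK3484862 against each of the other compounds in MV411, and the 3 differences between lines in the response to GSK3484862 (interaction terms).

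The 29 gene lists were tested with limma's camera at a preset correlation of 0.01 between genes, in 7 comparisons, with adjustment over the 203 tests. The 3819 genes with no residual spread were left out of these tests. Of the 203 tests, 76 passed, and 5 of the 76 also passed with the correlation estimated from the residuals. limma's fry was run beside it. After seeing the data the lists were also tested in the 3 differences between lines, with adjustment over those 87 tests. Of these 31 passed, and 1, the germline list for THP1 and MV411 (lower in THP1), also passed with an estimated correlation. The lists and the rules for naming genes were fixed before the data were examined. The named genes were, for each compound against DMSO, the 12 largest rises and 8 largest falls among called genes whose treated arrays both lay beyond both control arrays. The rule took the 5 highest and 5 lowest for the other comparisons, and for the genes shared by the 3 lines the 10 largest mean rises and 5 largest mean falls. For each list it took up to 2 called members with the highest and 2 with the lowest moderated t, or the member with the smallest p where none was called. DNMT1, DNMT3A, DNMT3B and UHRF1 were always included.

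The alternatives were a filter on dim genes, quantile normalization, centring on array medians, the mean of all probe sets of a gene, the probe set as the unit, a fit on the lines compared alone, eBayes with trend and robust options, a replicate block and leaving out each array. A fit without probe sets at the floor on all arrays was added after seeing the data. Alternatives that change a log offset apply to linear values and were not run. Comparisons in MV411 share the same 2 DMSO arrays, so 20 sets of unchanged MV411 arrays were simulated to give the overlap and correlation by chance. The DMSO arrays were simulated as well, with noise drawn for each probe set independently, so a joint shift of genes on the measured DMSO arrays is not covered.

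The fit was tested on simulated data with 200 changed genes among 19775. The changed genes were drawn only from genes with a mean well above the floor, so the shares recovered do not cover genes near it. For GSK3484862 in MV411 the fit recovered 59.7% of the genes changed 1.5-fold, 83.6% of those changed 2-fold and 98.5% of those changed 4-fold, and called 13 unchanged genes. For GSK3484862 in THP1 the shares were 50.7%, 92.5% and 98.5%, and for NOMO1 52.2%, 91.0% and 95.5%. A list shifted by 0.5 in the simulation was called in each of the 5 comparisons with DMSO, and 0 unshifted lists were. The simulated noise was independent between genes, so this run could not show how often correlated genes lead to false list calls.

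Replicate pairs correlated at r = 0.9965 to 0.999 across probe sets, which are not independent replicates. The difference between the 3' and 5' control probe sets lay between -0.14 and 0.30 for GAPDH and between 0.87 and 1.19 for ACTB. The number of arrays limits the precision.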

Results

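Gene expression was measured in 3 human acute myeloid leukemia cell lines after 96 hours of treatment (day 4). MV411 is a myelomonocytic leukemia line, and THP1 and NOMO1 are monocytic leukemia lines. All 3 received 0.1% DMSO, the vehicle, or 1 µM GSK3484862, which the series describes as a specific inhibitor of DNMT1, the enzyme that copies DNA methylation after replication. MV411 also received 0.4 µM DAC, the usual short name of the nucleoside drug decitabine, or 10 µM GSK3510477, which the series describes as an inactive compound. Each of the 8 groups had 2 arrays. Values are log2 expression, and differences are given as log2 difference ± SE from limma (n = 2 arrays per group).

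The first question was what the DNMT1 inhibitor changed in MV411. Members of the list of cancer-testis and germline genes, normally silent outside germ cells, were among the largest rises with GSK3484862. TKTL1, a transketolase-like gene, rose by 11.95 ± 0.18 from 2.62 ± 0.27 to 14.57 (SD, n = 2; adjusted p = 3.04e-09). The cancer-testis antigens MAGEA4 (9.50 ± 0.31), MAGEA6 (8.20 ± 0.37), MAGEB2 (7.72 ± 0.18) and MAGEA12 (7.40 ± 0.22) rose too. MAGEA4 held the same value, 3.08, on both MV411 DMSO arrays, so the size of its rises in MV411 is not exact. DAZL, a germ cell RNA-binding protein, rose by at least 7.28 ± 0.15 and MAEL, which acts in transposon silencing, by at least 7.28 ± 0.09. MAGEA1 rose by at least 6.95 ± 0.09, and TDRD9, a helicase of the piRNA pathway, by 7.91 ± 0.16. DAZL, MAEL and MAGEA1 lay at the floor in several groups, DAZL on all THP1 and NOMO1 arrays, so their SE can be too small. ZNF595 (9.82 ± 0.25), DCAF4L1 (8.19 ± 0.24) and OLIG1 (6.83 ± 0.16) completed the 12 largest rises. The largest falls were in the immediate early gene EGR3 (-5.88 ± 0.56), RGS16 (-4.68 ± 0.30), SLCO4C1 (-4.55 ± 0.33), RGCC (-4.39 ± 0.41), EGR1 (-4.20 ± 0.52), FCER2 (-4.10 ± 0.29), PDGFA (-4.09 ± 0.57) and ATF3 (-3.97 ± 1.03). All 8 also stood below DMSO with GSK3510477, the compound described as inactive. With it EGR3 (-5.70 ± 0.56), RGS16 (-3.18 ± 0.30), SLCO4C1 (-3.11 ± 0.33) and RGCC (-2.69 ± 0.41) were called. EGR1 (-2.80 ± 0.52), FCER2 (-2.67 ± 0.29) and PDGFA (-3.50 ± 0.57) were called too, and ATF3 (-2.83 ± 1.03) was not. All 8 stood below the same 2 DMSO arrays with DAC as well, RGS16 by the least (8.47 and 8.56, against 8.90 and 9.42 with DMSO). The call of ATF3 was lost without any 1 of the 4 arrays compared (-3.78 and -4.16 without DMSO replicate 1 or 2, -3.88 and -4.05 without GSK3484862 replicate 1 or 2). ATF3 stood at 7.28 and 3.15 on the 2 NOMO1 GSK3484862 arrays, which widens the SE that all groups share. When the MV411 arrays alone were fitted, ATF3 kept its call, as 0 of the 20 genes named by size lost theirs. EGR3 stood at 8.29 and 9.68 on the MV411 DMSO arrays and at 5.07 or lower on the 14 other arrays.

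Of the 71 measured cancer-testis and germline genes, 25 rose and 1 fell with GSK3484862 in MV411 (25 and 1 when adjusted over the list alone), and the list test passed (adjusted p = 8.66e-12), also with an estimated correlation (adjusted p = 0.00901). Of 14 MHC class II presentation genes, 10 rose and 0 fell (10 and 0 adjusted over the list alone), among them CIITA, the master regulator of the class (2.23 ± 0.08), and HLA-DPB1 (4.84 ± 0.17). That list had adjusted p = 5.37e-08, and adjusted p = 0.103 with an estimated correlation. Of 19 MHC class I presentation genes, 13 rose and 0 fell (14 and 0 adjusted over the list alone), with NLRC5 at 1.58 ± 0.13 (adjusted p = 6.67e-06, and 0.197 as the adjusted p with an estimated correlation). Of 48 monocyte and macrophage genes, 20 rose and 1 fell (21 and 1 adjusted over the list alone), including CX3CR1 (1.90 ± 0.11), while FCER1G fell (-1.53 ± 0.11). Its adjusted p was 0.000221, and the adjusted p with an estimated correlation was 0.16. Of 36 granulocyte genes, 11 rose and 1 fell, (11 and 1 adjusted over the list alone), including S100P (at least 3.07 ± 0.13), with adjusted p = 0.00758, and adjusted p = 0.209 with an estimated correlation. On both DMSO arrays S100P held its lowest value (3.34), and CIITA held the same value on both (4.47), so the size of its rise is not exact. Of 31 imprinted genes, 7 rose and 1 fell (7 and 2 adjusted over the list alone), including CDKN1C, a cell cycle inhibitor (2.73 ± 0.17), and PEG3 (2.16 ± 0.15), with adjusted p = 0.0305, and adjusted p = 0.123 with an estimated correlation.

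Genes of cell division and DNA replication fell with GSK3484862 in MV411. Of 40 cell division genes, 37 fell and 0 rose (39 and 0 adjusted over the list alone), including AURKB (-0.72 ± 0.06). Of 39 DNA replication genes, 33 fell and 0 rose (35 and 0 adjusted over the list alone), including CDC6 (-1.11 ± 0.10). The adjusted p-values were 1.87e-17 and 3.49e-17, and the adjusted p with an estimated correlation was 0.16 and 0.123. Of 27 cholesterol and sterol response genes, 20 fell and 0 rose (23 and 0 adjusted over the list alone), such as FDPS (-1.03 ± 0.06), with adjusted p = 1.99e-12, and adjusted p = 0.114 with an estimated correlation. Of 34 amino acid and ER stress response genes, 19 fell and 2 rose (20 and 4 adjusted over the list alone), with TRIB3 at -2.06 ± 0.11 (adjusted p = 3.89e-07, and adjusted p = 0.199 with an estimated correlation). Of 58 interferon-stimulated genes, 15 rose and 8 fell (16 and 10 adjusted over the list alone), and this list did not pass (adjusted p = 0.382). PARP12, with the same value on both DMSO arrays (3.63), rose by 2.17 ± 0.13 and IFIT3 fell (-3.29 ± 0.32).

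The other lists did not pass in this comparison. Counts of members that rose and fell were 3 and 0 of 28 viral RNA and DNA sensing genes, 7 and 8 of 36 p53 target genes, 3 and 9 of 33 stem and progenitor leukemia genes, 6 and 5 of 27 DNA methylation machinery genes, and 5 and 5 of 17 decitabine uptake and activation genes. They were 5 and 6 of 33 apoptosis regulators, 3 and 9 of 42 NF-kB and inflammatory cytokine genes, 1 and 0 of 23 protocadherin cluster genes, and 4 and 2 of 43 genes often silenced by promoter methylation in cancer. They were 9 and 3 of 30 xenobiotic response genes, 5 and 1 of 15 core histone genes, and 0 and 0 of 34 ribosomal protein genes, of which 2 were higher at an unadjusted limma p under 0.05. Among markers of other cell types they were 1 and 2 of 29 B cell genes, 2 and 3 of 37 T and NK cell genes, 2 and 1 of 29 erythroid genes, 3 and 3 of 28 megakaryocyte and platelet genes, 4 and 1 of 18 mast cell and eosinophil genes, and 2 and 1 of 27 epithelial and fibroblast genes.

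In total 4191 of 19775 genes were called with GSK3484862 in MV411, 2277 higher and 1914 lower, of which 717 were at least 2-fold higher and 241 at least 2-fold lower. With the probe set as the unit the count was 7313. The split turned after centring on array medians (2176 higher and 2218 lower). It was near even with quantile normalization (2220 and 2153) and the mean of probe sets (2049 and 2040). DNMT3A fell (-0.70 ± 0.06, adjusted p = 6.48e-05), although the mean of its 3 probe sets did not pass. UHRF1, which recruits DNMT1 to replicating DNA, fell (-0.28 ± 0.06, adjusted p = 0.0116), a call lost without DMSO replicate 2 (-0.24) or GSK3484862 replicate 2 (-0.26) and when the MV411 arrays alone were fitted. The differences of DNMT1 (-0.17 ± 0.11) and DNMT3B (-0.24 ± 0.13) did not pass.

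**Figure D1:**
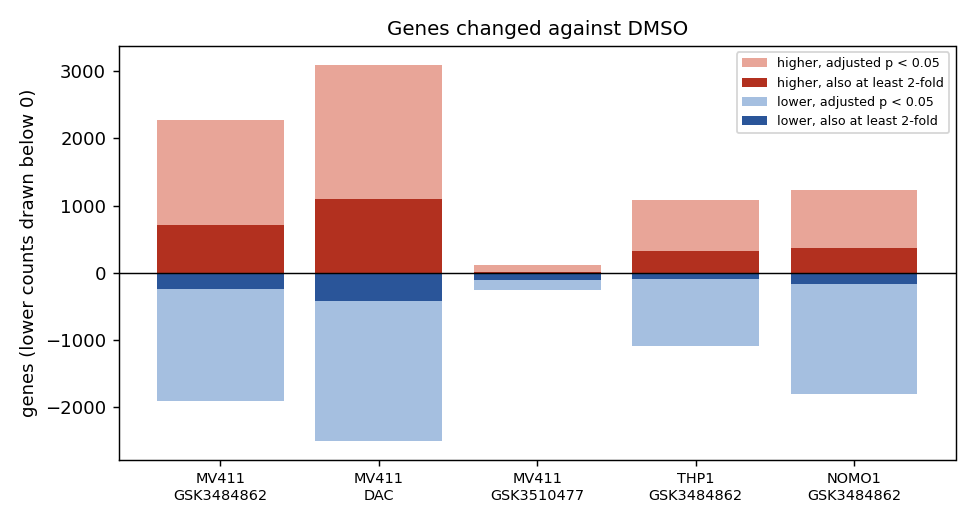
Bars give the number of genes called higher (above 0) or lower (below 0) than DMSO in each comparison, with the dark part at least 2-fold. GSK3510477 changed 372 genes and GSK3484862 4191 in the same line.

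**Figure D2:**
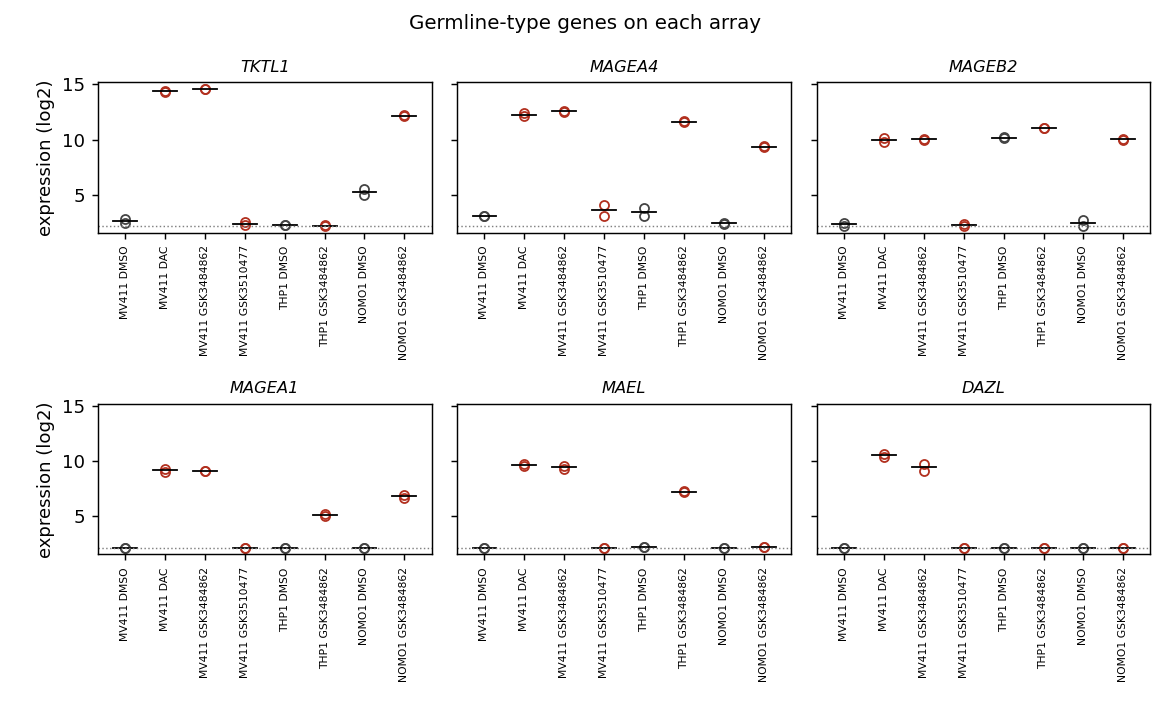
Each circle is the log2 expression of 1 array, black for DMSO and red for a compound, the bar is the mean of 2 arrays and the dotted line is the floor of the table. The mean of MAGEA4 lay between 2.39 and 3.59 in the DMSO and GSK3510477 groups and between 9.36 and 12.58 in the others.

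DAC was given to MV411 as a second DNA methylation inhibitor. The largest rises with DAC included TKTL1 at 11.75 ± 0.18, ZNF595 at 9.44 ± 0.25, MAGEA4 at 9.18 ± 0.31, TDRD9 at 8.41 ± 0.16, MAGEA6 at 8.36 ± 0.37, DCAF4L1 at 8.07 ± 0.24 and MAGEB2 at 7.65 ± 0.18. DAZL rose by at least 8.36 ± 0.15 and MAEL by at least 7.47 ± 0.09. MAGEA1 rose by at least 7.0 ± 0.09 and the scavenger receptor STAB1 by at least 6.93 ± 0.13. DAZL, MAEL, MAGEA1 and STAB1 lay at the floor in several groups, so their SE can be too small. ALOX5, which makes leukotrienes, rose by 7.07 ± 0.18. The largest falls were in EGR3 (-5.01 ± 0.56), SLCO4C1 (-4.61 ± 0.33), GAL (-4.54 ± 0.35), RGCC (-4.51 ± 0.41), SLC38A5 (-4.13 ± 0.35), OLMALINC (-3.92 ± 0.14), the sterol enzyme DHCR7 (-3.45 ± 0.20) and CBS (-3.44 ± 0.32). RGCC and OLMALINC held the same value on both DAC arrays (2.79 and 3.82), the lowest of each gene, so these 2 falls are at least of the size given and their ranks are open. DNMT1 fell (-0.42 ± 0.11, adjusted p = 0.0154), a call lost without DAC replicate 1 (-0.36) or DMSO replicate 1 (-0.37), and UHRF1 fell (-1.02 ± 0.06, adjusted p = 6.03e-06). DNMT3A fell (-0.80 ± 0.06, adjusted p = 1.62e-05). DNMT3B fell (-0.42 ± 0.13, adjusted p = 0.0347), a call lost without DAC replicate 2 (-0.31) or DMSO replicate 2 (-0.26), with the trend and robust options, with the probe set as the unit and when the MV411 arrays alone were fitted.

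With DAC, 32 of 71 germline genes rose and 1 fell (32 and 1 adjusted over the list alone), with adjusted p = 4.06e-13, and adjusted p = 0.00901 with an estimated correlation. All 40 cell division genes and all 39 DNA replication genes fell, with AURKB at -1.26 ± 0.06 and POLA1 at -1.66 ± 0.07 (adjusted p = 3.74e-21 and 1.55e-22, and adjusted p = 0.133 and 0.103 with an estimated correlation). Interferon-stimulated genes rose in 34 of 58 cases and fell in 2 (40 and 3 adjusted over the list alone), led by IFI27 (5.85 ± 0.22), with adjusted p = 2.08e-08, and adjusted p = 0.16 with an estimated correlation. Of 36 p53 target genes, 18 rose and 2 fell (19 and 2 adjusted over the list alone), including TP53INP1 (2.73 ± 0.10), with adjusted p = 0.000553, and adjusted p = 0.0534 with an estimated correlation. Of 27 sterol response genes, 23 fell and 0 rose, with adjusted p = 4.17e-16, and adjusted p = 0.0972 with an estimated correlation. DAC changed 5601 genes, 3098 higher and 2503 lower, with 1093 at least 2-fold higher and 422 at least 2-fold lower. With the probe set as the unit the count was 9904. After centring each array on its median it was 11873, with 3156 higher and 8717 lower, and 4877 of the 6341 genes called only then were at the floor on all arrays compared.

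GSK3484862 and DAC were compared directly at 1 µM and 0.4 µM, doses that differ. Of the 717 genes at least 2-fold higher with GSK3484862, 683 were also called higher with DAC. Both compounds raised 1859 genes and lowered 1499, and 58 went opposite ways, where independent lists of these sizes would share 357 and 242. In simulated unchanged MV411 arrays, with the shared DMSO arrays simulated too, 0.55 and 2.2 genes were shared on average. The noise was drawn for each probe set alone, so a joint shift of many genes on the measured DMSO arrays could not appear there. The differences correlated across genes at r = 0.85, with 0.50 in the simulation, and genes are not independent replicates. The covariance was 0.342 against 0.0086 simulated. The 2 DMSO arrays could not be split with 2 in each part, so part of the excess may come from the shared controls.

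**Figure D3:**
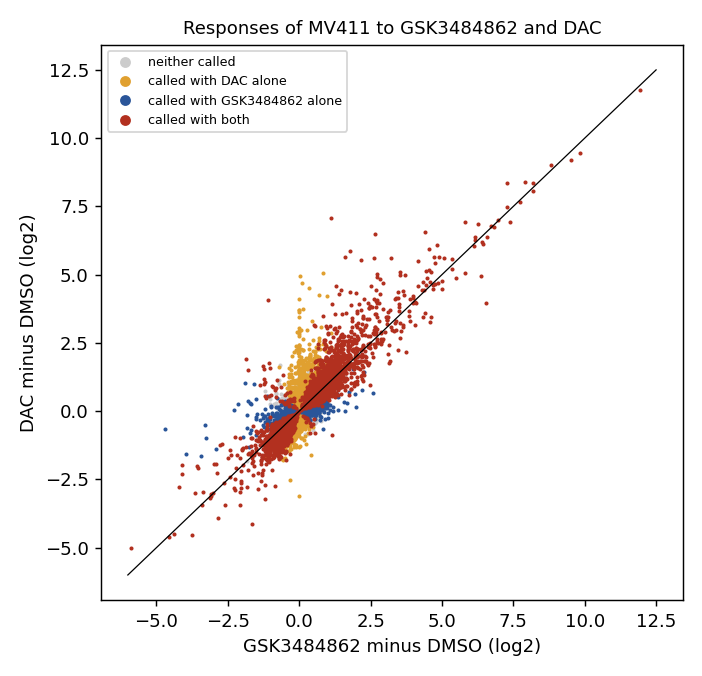
Each point is a gene, with its log2 difference from DMSO with GSK3484862 (x axis) and DAC (y axis) in MV411, coloured by which comparison called it, and the line marks equal values. Across genes r was 0.85.

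Between the 2 compounds 2385 genes differed, 1131 higher and 1254 lower with GSK3484862, of which 73 and 359 differed at least 2-fold (44 and 239 with the mean of probe sets, and 211 of the lower under the filter on dim genes). Lower with GSK3484862 than with DAC were ALOX5 (-5.95 ± 0.18), the chemokine CCL2 (-5.16 ± 0.30), PDK4 (-4.95 ± 0.27), RHEX (-4.60 ± 0.21) and CYP1B1 (-4.25 ± 0.52). Higher were the cholesterol transporter ABCA1 (3.09 ± 0.17), the granule enzyme MPO (2.57 ± 0.37), SLC38A5 (2.47 ± 0.35), SREBF1 (2.18 ± 0.13) and SLC22A16 (2.03 ± 0.27). Of 36 p53 target genes, 15 were lower and 2 higher with GSK3484862, with FAS at -1.90 ± 0.12, and this list passed (adjusted p = 5.68e-09), also with an estimated correlation (adjusted p = 0.00901). Of 58 interferon-stimulated genes, 34 were lower and 1 higher (adjusted p = 9.49e-16, and adjusted p = 0.0972 with an estimated correlation). Of 39 DNA replication genes, 26 were higher and 0 lower with GSK3484862 (adjusted p = 4.71e-19, and adjusted p = 0.117 with an estimated correlation). The count of genes that differed was 1410 with the trend and robust options, 1414 without GSK3484862 replicate 1, 1181 without GSK3484862 replicate 2 and 1314 without DAC replicate 2. UHRF1 was higher with GSK3484862 than with DAC (0.75 ± 0.06, adjusted p = 0.000228), and DNMT1 (0.25 ± 0.11), DNMT3A (0.11 ± 0.06) and DNMT3B (0.18 ± 0.13) did not pass. The calls of SLC38A5 and SLC22A16 were lost when the MV411 arrays alone were fitted.

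GSK3510477, the compound described as inactive, was given to MV411 at 10 µM, a dose that differs from those of the other compounds. The rises were led by PIR (3.04 ± 0.26) and NQO1 (1.76 ± 0.19), both known targets of the oxidative stress factor NRF2, for which no list was tested. PLCB4 (1.5 ± 0.20), MNDA (1.44 ± 0.22), TSPAN33 (1.20 ± 0.22), EPHX1 (1.15 ± 0.17), TFEC (1.07 ± 0.08) and S100P (at least 0.98 ± 0.13) also rose. GCLM of glutathione synthesis (0.84 ± 0.08) was the last of the 12 largest rises, behind others not given here. The falls were led by EGR3 (-5.70 ± 0.56), the interferon-induced IFIT3 (-5.54 ± 0.32), IL4I1 (-4.22 ± 0.67), PDGFA (-3.50 ± 0.57), the stress gene DDIT4 (-3.48 ± 0.20), MIR210HG (-3.42 ± 0.61), RHOB (-3.29 ± 0.39) and IGLC1 (-3.20 ± 0.56). EGR3 held the same value on both GSK3510477 arrays (3.28), so the size of its fall is not exact. IL4I1 stood at 5.98 and 8.42 on the 2 DAC arrays, which widens the SE that all groups share. Of the 20 genes named by size, 9 lost the call on leaving out 1 array and 15 when the MV411 arrays alone were fitted. Of those given here, the first was so for IL4I1 without any 1 array (-4.33 and -4.11 without DMSO replicate 1 or 2, -4.28 and -4.15 without GSK3510477 replicate 1 or 2). Without DMSO replicate 1 it was so for PDGFA (-3.65), TSPAN33 (1.07) and EPHX1 (1.16). Without DMSO replicate 2 it was so for PDGFA (-3.36), MIR210HG (-2.93), IGLC1 (-2.67), MNDA (1.22), TSPAN33 (1.32) and EPHX1 (1.14). Without GSK3510477 replicate 1 it was so for PDGFA (-3.11), MIR210HG (-3.36), IGLC1 (-3.40), MNDA (1.30), TSPAN33 (0.92) and EPHX1 (0.99), and without GSK3510477 replicate 2 for MIR210HG (-3.48) and IGLC1 (-3.0).

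With GSK3510477, 0 of 71 germline genes were called (1 at an unadjusted limma p under 0.05). Of 40 cell division genes 0 were called (1 at an unadjusted limma p under 0.05), and the list did not pass (adjusted p = 0.232). Of 39 DNA replication genes 0 were called (2 at an unadjusted limma p under 0.05), but the list as a whole passed upward, with a median difference of 0.11 (adjusted p = 0.00204, and adjusted p = 0.589 with an estimated correlation). Of 58 interferon-stimulated genes, 17 fell and 0 rose (28 and 1 adjusted over the list alone), with adjusted p = 4.1e-21, and adjusted p = 0.0643 with an estimated correlation. Of 27 sterol response genes, 12 fell and 0 rose (19 and 0 adjusted over the list alone), with adjusted p = 5.01e-22, and adjusted p = 0.0643 with an estimated correlation.

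GSK3510477 changed 372 genes, 123 higher and 249 lower, of which 7 were at least 2-fold higher and 114 at least 2-fold lower. The balance turned when either GSK3510477 array was left out, with 337 higher and 197 lower without replicate 1 and 392 and 185 without replicate 2, while at least 2-fold they were 6 and 95, and 18 and 87. With the mean of probe sets 73 were at least 2-fold lower. DNMT1 (0.12 ± 0.11), DNMT3A (-0.07 ± 0.06), DNMT3B (-0.41 ± 0.13) and UHRF1 (0.03 ± 0.06) did not pass. The count was 120 when the MV411 arrays alone were fitted, with 37 at least 2-fold lower, and 186 with the trend and robust options. With the replicate block it was 214, with 61 at least 2-fold lower. GSK3484862 and GSK3510477 both raised 59 genes and lowered 134, and 63 went opposite ways, where independent lists would share 14.2 and 24.1 and the simulation gave 0.1 and 2.15. Across genes r was 0.21 (0.50 simulated) and the covariance 0.0298 (0.00871 simulated). DAC and GSK3510477 both raised 63 genes and lowered 97, and 105 went opposite ways, where independent lists would share 19.3 and 31.5 and the simulation gave 0.35 and 2.25. For this pair r was 0.046 (0.50 simulated) and the covariance 0.00781, no higher than the 0.00862 simulated. Part of the shared calls of both pairs may come from the shared controls. Of the 717 genes at least 2-fold higher with GSK3484862, 24 were called higher with GSK3510477 and 699 were still called when GSK3484862 was compared with GSK3510477. Of the 241 at least 2-fold lower, 72 were called lower with GSK3510477 and 150 were still called. That direct comparison called 4569 genes, 2346 higher and 2223 lower with GSK3484862, led by TKTL1 (12.18 ± 0.18), ZNF595 (9.60 ± 0.25), MAGEA4 (9.0 ± 0.31), DCAF4L1 (8.48 ± 0.24) and MAGEA6 (8.24 ± 0.37). Lowest were GAL (-3.48 ± 0.35), ICAM2 (-2.56 ± 0.19), CBS (-2.50 ± 0.32), INCENP (-2.48 ± 0.44) and RPGRIP1L (-2.31 ± 0.48), whose call was lost without GSK3484862 replicate 2 (-1.99). DNMT3A (-0.63 ± 0.06, adjusted p = 0.000114) was lower, although the mean of its probe sets did not pass, and so was UHRF1 (-0.31 ± 0.06, adjusted p = 0.00638), whose call was lost when the MV411 arrays alone were fitted. DNMT3B (0.17 ± 0.13) did not pass, nor did DNMT1 (-0.29 ± 0.11), which passed under the filter on dim genes and after centring on array medians (-0.34). Of 71 germline genes, 25 were higher and 1 lower (adjusted p = 1.19e-11, and adjusted p = 0.00901 with an estimated correlation). In this comparison 28 of 58 interferon-stimulated genes were higher and 0 lower (adjusted p = 2.36e-08, and adjusted p = 0.16 with an estimated correlation). The count of genes was 8325 with the probe set as the unit and 10988 after centring on array medians, with 2507 higher and 8481 lower.

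In THP1, GSK3484862 raised MAGEA4 (8.20 ± 0.31), ZNF595 (7.45 ± 0.25), DCAF4L1 (6.64 ± 0.24) and the interferon-induced IFI27 (6.53 ± 0.22). COX8C (6.10 ± 0.09), PAX8-AS1 (5.29 ± 0.09), MAEL (5.03 ± 0.09), OTP (4.99 ± 0.10), LINC02204 (4.96 ± 0.17) and C12orf56 (4.35 ± 0.18) rose too. SELENBP1 rose by at least 5.08 ± 0.42 and the imprinted gene DIRAS3 by at least 4.66 ± 0.02. MAEL held the same value, 2.23, on both THP1 DMSO arrays. The largest falls were in RNF182 (-3.05 ± 0.30), EML1 (-2.88 ± 0.22), SLC16A10 (-2.81 ± 0.20), ANK3 (-2.65 ± 0.36), ITM2A (-2.45 ± 0.20), HMX2 (-2.42 ± 0.06), NPTX2 (-2.26 ± 0.16) and PAX5, a B cell transcription factor (-2.25 ± 0.23). DNMT3A fell (-0.43 ± 0.06), although the mean of its probe sets did not pass, and DNMT1 (0.01 ± 0.11), DNMT3B (-0.20 ± 0.13) and UHRF1 (-0.12 ± 0.06) did not pass. Of 58 interferon-stimulated genes, 29 rose and 0 fell (36 and 0 adjusted over the list alone), with adjusted p = 6.24e-18, and adjusted p = 0.0875 with an estimated correlation. Of 48 monocyte and macrophage genes, 19 rose and 0 fell, including VSIG4 (3.04 ± 0.17), with adjusted p = 6.63e-10, and adjusted p = 0.071 with an estimated correlation. Of 71 germline genes, 11 rose and 1 fell (adjusted p = 0.00245, and adjusted p = 0.114 with an estimated correlation). Of 39 DNA replication genes, 19 fell and 0 rose (adjusted p = 4.07e-14, and adjusted p = 0.16 with an estimated correlation), and of 40 cell division genes 6 fell and 0 rose (adjusted p = 0.00144, and adjusted p = 0.628 with an estimated correlation). In total 2175 genes changed, 1081 higher and 1094 lower, with 321 and 92 at least 2-fold (165 and 35 under the filter on dim genes, 213 and 59 with the mean of probe sets). The count was 3277 with the probe set as the unit, 62 when the 4 THP1 arrays were fitted alone (15 higher and 3 lower at least 2-fold), 1228 with the trend and robust options and 1294 without GSK3484862 replicate 1. Of the 20 genes named by size, 13 lost the call in the fit of the THP1 arrays alone. DIRAS3, RNF182, EML1, SLC16A10 and ITM2A lay at the floor on all arrays of the other lines, so their SE can be too small.

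In NOMO1, GSK3484862 raised ZNF595 (9.77 ± 0.25), MAGEB2 (7.57 ± 0.18), MAGEA4 (6.96 ± 0.31) and TKTL1 (6.91 ± 0.18). Granulocyte genes were among the largest rises, with ARG1, an enzyme of neutrophil granules, at 6.06 ± 0.34 and CEACAM8, a granulocyte surface protein, at 4.68 ± 0.25. OTP (5.68 ± 0.10), ADGRG3 (5.45 ± 0.09), LOXL1 (5.09 ± 0.10), NAV3 (4.88 ± 0.31), DCAF4L1 (4.87 ± 0.24) and VSTM1 (4.83 ± 0.12) rose too. LOXL1 held the same value, 2.21, on both NOMO1 DMSO arrays. The largest falls were in CSRP3 (-4.11 ± 0.21), IL12A (-4.08 ± 0.14), RXFP1 (-2.79 ± 0.25), SHISA2 (-2.71 ± 0.10), NOG (-2.70 ± 0.21), GZMA (-2.64 ± 0.12), MANEAL (-2.62 ± 0.16) and NTS (-2.55 ± 0.33). DNMT3A fell (-0.53 ± 0.06), with 1 of its 3 probe sets called the opposite way and no call for their mean or in the fit of the NOMO1 arrays alone. DNMT1 (-0.16 ± 0.11), DNMT3B (-0.02 ± 0.13) and UHRF1 (-0.05 ± 0.06) did not pass. Of 36 granulocyte genes, 20 rose and 0 fell (22 and 0 adjusted over the list alone), and the list held with an estimated correlation (adjusted p = 0.0258). Of 48 monocyte and macrophage genes, 19 rose and 2 fell, with CD14 at 4.46 ± 0.16 (adjusted p = 2.08e-08, and adjusted p = 0.0972 with an estimated correlation). Of 71 germline genes, 13 rose and 0 fell (adjusted p = 2.57e-06, and adjusted p = 0.0513 with an estimated correlation). Of 33 stem and progenitor leukemia genes, 11 fell and 1 rose, including FLT3 (-1.65 ± 0.07), with adjusted p = 0.00183, and adjusted p = 0.235 with an estimated correlation. Markers of other blood cells moved in NOMO1 too. Of 18 mast cell and eosinophil genes, 7 rose and 1 fell (adjusted p = 4.61e-06, and adjusted p = 0.0513 with an estimated correlation), and of 37 T and NK cell genes 7 rose and 1 fell (adjusted p = 0.0081, and adjusted p = 0.235 with an estimated correlation). In total 3032 genes changed, 1228 higher and 1804 lower, with 370 and 173 at least 2-fold (147 and 83 under the filter on dim genes, and 113 of the lower with the mean of probe sets). The excess of lower calls turned without GSK3484862 replicate 2, with 1335 higher and 1164 lower, and was smaller with quantile normalization (1324 and 1418). The count was 4649 with the probe set as the unit, 274 when the 4 NOMO1 arrays were fitted alone (56 higher and 16 lower at least 2-fold) and 2006 with the trend and robust options. Of the 20 genes named by size, 11 lost the call in the fit of the NOMO1 arrays alone. ARG1, ADGRG3, VSTM1, CEACAM8, CSRP3, IL12A, SHISA2, GZMA and NTS lay within 0.01 of the floor on all arrays of the other lines, so their SE can be too small. ARG1 stood at 10.63 and 9.36 on the 2 NOMO1 GSK3484862 arrays.

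**Figure D4:**
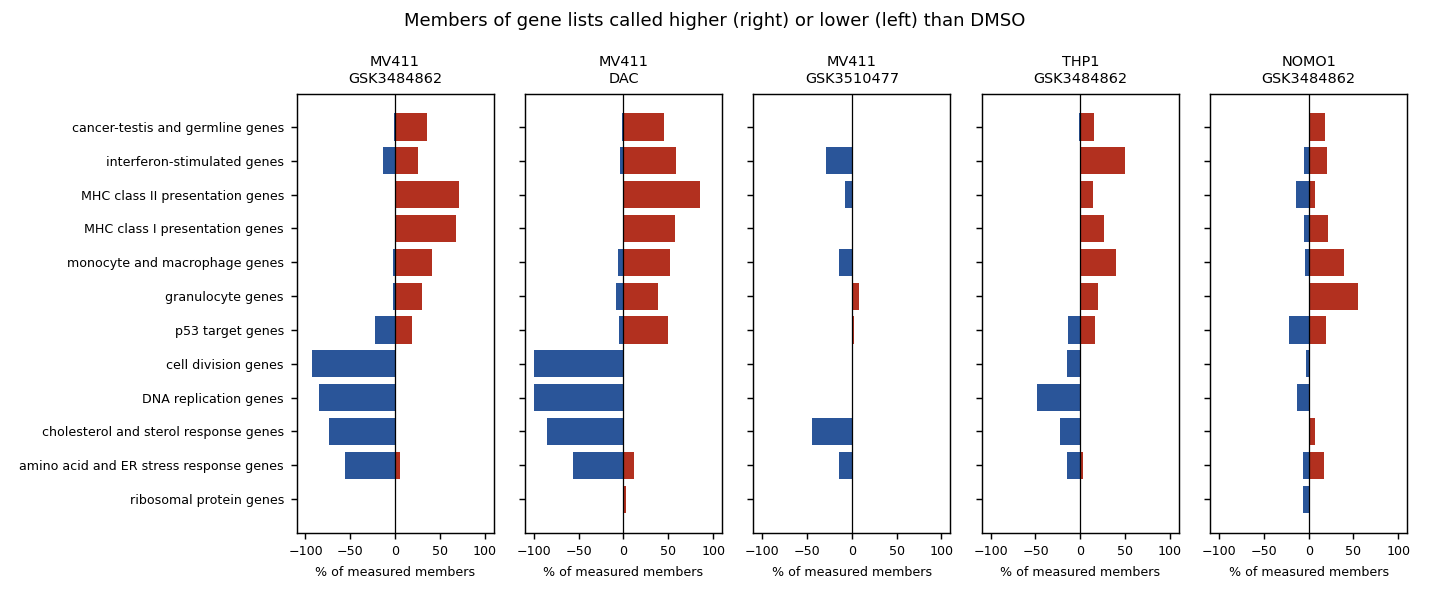
Bars give the percent of measured members of 12 lists called higher (right) or lower (left) than DMSO. Cell division and DNA replication genes fell in MV411 with GSK3484862 (37 of 40 and 33 of 39) and DAC (40 and 39), and 0 were called with GSK3510477.

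Across the 3 lines, 515 genes changed in the same direction with GSK3484862, 232 higher and 283 lower, where independent lists would share 7.73 and 9.66. These comparisons share no arrays, but the spread of each gene was estimated over all 16 arrays, which favours the same genes in each line, so the values for independent lists are not those of no change. The largest mean rises were in ZNF595 (9.01), MAGEA4 (8.22), DCAF4L1 (6.56), OTP (5.71), MAGEB2 (5.39), MAGEA1 (at least 4.84, at the floor with DMSO in all 3 lines), TDRD9 (3.80), IL23R (3.61), PRAME (3.49) and NFE4 (3.32). MAGEB2 and PRAME were already high in THP1 with DMSO, at 10.17 and 10.38, and rose there by 0.89 ± 0.18 and 1.26 ± 0.20. The largest mean falls were in NKD2 (-1.59), GPR183 (-1.55), COL27A1 (-1.37), ONECUT2 (-1.31) and MBNL1-AS1 (-1.17). The count was 2 when each line was fitted alone, 243 with the trend and robust options and 314 or 331 without THP1 GSK3484862 replicate 1 or 2.

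The response to GSK3484862 differed between THP1 and MV411 in 2239 genes, between NOMO1 and MV411 in 2610 and between NOMO1 and THP1 in 1450. The response of TKTL1 in THP1 minus that in MV411 was -11.97 ± 0.25, a size that is not exact since TKTL1 held the same value, 2.22, on both THP1 DMSO arrays. That of DAZL was -7.28 ± 0.21, a value set by the floor, at which DAZL lay on all THP1 arrays and in MV411 with DMSO. For ARG1 the response in NOMO1 exceeded those in MV411 and in THP1 by 6.06 ± 0.47 each, values also set by the floor, at which it lay in those 2 lines. IFI27 rose more in THP1 than in MV411 by 4.75 ± 0.31. EGR3, which fell in MV411, differed by 5.16 ± 0.79 in THP1 and by 7.18 ± 0.79 in NOMO1. With DMSO, EGR3 stood at 4.78 and 3.29 in THP1 and at 3.28 and 3.35 in NOMO1, against 8.29 and 9.68 in MV411. It thus had little room to fall in THP1 and NOMO1, and in MV411 it also stood below DMSO with GSK3510477 and DAC. The differences between lines in DNMT1, DNMT3A, DNMT3B and UHRF1 did not pass. That of DNMT3A passed with quantile normalization for THP1 and MV411 (0.30) and for NOMO1 and MV411 (0.30), and for THP1 and MV411 also under the filter on dim genes (0.26). For THP1 and MV411 the count was 3500 with the probe set as the unit, 1289 with the trend and robust options and 1395 without MV411 GSK3484862 replicate 2. For NOMO1 and MV411 it was 4277 with the probe set as the unit. For NOMO1 and THP1 it was 476 when their arrays alone were fitted and 693 with the trend and robust options. By camera, the germline list was lower in the THP1 response than in that of MV411 (adjusted p = 9.48e-10, 0.0274 with an estimated correlation). For NOMO1 minus MV411 the median was 0.50 for cell division, 1.07 for sterol response and -1.96 for MHC class II genes. Their camera adjusted p was 3.19e-14, 1.23e-13 and 1.52e-07, and 0.255, 0.135 and 0.135 with an estimated correlation.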

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

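The tests of the DMSO arrays as a whole, of genes chosen against 1 DMSO array, of quantile normalization, of the GSK3510477 reference and of the gene lists between lines were chosen only after the related results had been seen.

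The response to GSK3484862 differed between lines by an interaction test in 2239 genes for THP1 and MV411, 2610 for NOMO1 and MV411 and 1450 for NOMO1 and THP1. In THP1 against MV411 the highest differences (log2) were EGR3 (5.16), C12orf56 (4.90), SLCO4C1 (4.87), IFI27 (4.75) and DIRAS3 (4.66), and the lowest were TKTL1 (-11.97), MPO (-7.83), MAGEA6 (-7.38), DAZL (-7.28) and MAGEA12 (-7.04). In NOMO1 against MV411 the highest were EGR3 (7.18), ARG1 (6.06), ADGRG3 (5.45), EGR1 (5.38) and SLCO4C1 (4.86), and the lowest were DAZL (-7.28), MAEL (-7.22), TDRD9 (-7.17), COX7B2 (-6.70) and MAGEA12 (-6.37). In NOMO1 against THP1 the highest were TKTL1 (6.93), MAGEB2 (6.68), ARG1 (6.06), ADGRG3 (5.45) and LOXL1 (5.07), and the lowest were IFI27 (-6.52), COX8C (-6.0), PAX8-AS1 (-5.27), LINC02204 (-5.13) and SELENBP1 (-5.08). At least 1 group compared lay at the floor for DIRAS3, DAZL, ARG1, ADGRG3, MAEL, COX7B2, LOXL1, PAX8-AS1 and SELENBP1, so these differences are set by the floor and are not exact. Nor are those of TKTL1, MAGEA12, IFI27 and LINC02204 with values repeated on both arrays of a group. EGR3 was already low with DMSO in THP1 (4.78 and 3.29) and NOMO1 (3.28 and 3.35), so it had little room to fall there. Other genes were already high with DMSO in 1 of the lines compared. These were TDRD9 in NOMO1 (mean 8.45), MAGEB2 in THP1 (mean 10.17) and C12orf56 in MV411 (9.82 and 9.85). Their differences thus do not mean that the gene stayed silent in that line. In MV411, EGR3, EGR1 and SLCO4C1 also stood below DMSO with GSK3510477 and DAC, so their falls there were not particular to GSK3484862. Among the 11721 probe sets without a gene symbol, which no comparison of genes used, 1 was at least 2-fold higher and 1 at least 2-fold lower with GSK3484862 in all 3 lines.

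The 114 genes at least 2-fold lower with GSK3510477 had a median difference of -1.64 with it and of -0.96 with GSK3484862, and 60 were also called lower with GSK3484862. Had the 2 DMSO arrays stood apart from all treated arrays, these genes would be about as low with DAC, but the median DAC difference was 0.0302 of that with GSK3510477 (95% bootstrap interval -0.321 to 0.359), and 0.16 without 12 interferon genes. DAC moved members both ways, 42 lower and 43 higher, and 40 of the 60 genes called lower with both GSK compounds were also called lower with DAC. A median over all 114 genes cannot tell a DMSO shift partly hidden by rises with DAC from no shift, so a DMSO shift stays open. Leaving out either DMSO array left at least 0.869 of the median GSK3484862 difference, but these genes were chosen on both arrays, and genes chosen against 1 DMSO array kept 0.723 and 0.897 of it against the other, the lower with a 95% bootstrap interval of 0.488 to 0.92, which does not clear the 0.5 set as the bound, so a role of 1 array stays open. A response shared by the 2 GSK compounds stays open as a hypothesis and was not tested apart from these values.

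GSK3484862 gave more 2-fold rises than falls in all 3 lines (74.8%, 77.7% and 68.1% rises in MV411, THP1 and NOMO1). The floor of the table could hide falls, but among genes whose lower group mean was at least 4 the lowest share of rises was 63.6%, with a 95% exact binomial interval of 58.2% to 68.8% in NOMO1. After quantile normalization the lowest share was 70.1%, so a plain upward shift of treated arrays is argued against too. The intervals treat genes as independent, which they are not. Over all called genes of the main fit the rises were 54.3%, 49.7% and 40.5%, so in that fit THP1 and NOMO1 had an excess of rises among 2-fold changes only. These shares depended on the processing. With the trend and robust options they were 56.8% in THP1 and 44.4% in NOMO1, and after centring on array medians 49.5% in MV411. Whether loss of DNA methylation is behind the excess of 2-fold rises stays open as a hypothesis, since methylation was not measured.

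The response of the interferon-stimulated genes to GSK3484862 in THP1 minus that in MV411 had a median of 0.55 over 58 genes (95% bootstrap interval 0.187 to 0.852), and the list passed for this difference (adjusted p = 2.36e-07), but not with an estimated correlation (adjusted p = 0.255). With GSK3510477 in place of DMSO as the MV411 reference the median fell to -0.026, which is -0.0474 of its former value. GSK3510477 itself stood below DMSO on this list (median -0.43, interval -0.617 to -0.174), so a high DMSO level and a fall with GSK3510477 cannot be told apart. This condition on GSK3510477 was added after the value had been seen, since the test alone pointed to a high DMSO level. The list was not near its highest level in MV411 before treatment, since its median level in that line was 6.15 with DMSO and 7.69 with DAC. The median of MV411 DMSO minus treated THP1 was -1.0 (interval -1.69 to -0.493), but a level in another line is no limit for MV411. The intervals for this list treat its genes as independent, which they are not, and a difference between the lines stays open.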

How the results depend on the processing

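The fit without probe sets at the floor on all arrays was chosen after seeing the data. With 2 arrays per group, and a lone array assumed to vary like the other groups when its partner was left out, counts depended on how the spread was estimated. Fitted on the lines compared alone, the count of genes changed was 120 for GSK3510477, 62 in THP1, 274 in NOMO1, 476 for NOMO1 against THP1 and 2 in all 3 lines. These fits had fewer arrays to estimate the spread, and left out groups of the other lines at the floor, which have no spread. Of these calls, 79 for GSK3510477, 39 in THP1 and 200 in NOMO1 were also made with all arrays. Counts alone thus do not show that the same genes were called. With the trend and robust options the count was 186 for GSK3510477, 1228 in THP1, 2006 in NOMO1, 1410 between GSK3484862 and DAC, 1289 for THP1 against MV411, 693 for NOMO1 against THP1 and 243 in all 3 lines, and the cause was not tested. With the probe set as the unit, which tests more features, it was 7313 for GSK3484862 and 9904 for DAC in MV411, 3277 in THP1, 4649 in NOMO1, 8325 between GSK3484862 and GSK3510477, 3500 for THP1 against MV411, 4277 for NOMO1 against MV411 and 5654 shared by GSK3484862 and DAC.

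After centring on array medians it was 11873 for DAC (3156 higher, 8717 lower, against 3098 and 2503) and 10988 between GSK3484862 and GSK3510477 (2507 higher, 8481 lower, against 2346 and 2223). Of the genes called only then, 4877 of 6341 and 4734 of 6454 lay at the floor on all arrays compared, where centring moves constant values. Deviations of same-numbered arrays correlated at 0.16 to 0.56 within lines and from -0.31 to 0.34 between lines, and 2 replicates per group do not settle whether the numbers pair arrays. With the replicate block the count for GSK3510477 was 214 (85 higher and 129 lower, 61 of these at least 2-fold), and no other count moved by over 1.5 times. With the trend and robust options the GSK3510477 calls were 22.0% higher against 33.1%. Without DMSO replicate 1 or 2 the share was 22.5% and 16.3%, but without GSK3510477 replicate 1 or 2 it turned, to 63.1% and 67.9%. In NOMO1 the share was 53.4% without GSK3484862 replicate 2 and 48.3% with quantile normalization, against 40.5%. Without NOMO1 GSK3484862 replicate 1 or 2 it was 53.7% and 58.7% for NOMO1 against THP1 (42.2% with all arrays), and without replicate 2 46.1% for NOMO1 against MV411 (35.4%). Splits near even, as in THP1, changed sides under several settings, and that of GSK3484862 in MV411 turned after centring on array medians (2176 higher and 2218 lower). Other counts of called genes stayed within 1.5 times under quantile normalization, the dim filter, the mean of probe sets and the fit without probe sets at the floor. Counts of 2-fold changes moved further. Under the dim filter 165 rose and 35 fell in THP1 and 147 and 83 in NOMO1, and 211 were lower between GSK3484862 and DAC. With the mean of probe sets these were 213 and 59 in THP1, 113 falls in NOMO1, 73 falls for GSK3510477 (37 when the MV411 arrays alone were fitted), and 44 and 239 between GSK3484862 and DAC. With an estimated correlation 5 of the 76 list tests passed.

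Leaving out 1 array gave 2856 to 3672 genes for GSK3484862 in MV411, 4406 to 5062 for DAC, 382 to 577 for GSK3510477, 1294 to 2260 in THP1, 2286 to 2499 in NOMO1, 1181 to 2136 between GSK3484862 and DAC, 3120 to 4010 between GSK3484862 and GSK3510477, 1395 to 2531, 1955 to 2600 and 1103 to 1706 for the differences of THP1 from MV411, NOMO1 from MV411 and NOMO1 from THP1, 314 to 500 in all 3 lines, 2413 to 3087 shared by GSK3484862 and DAC and 74 to 81 list tests. Of 684 called results of named genes, 125 lost the call on leaving out 1 array and 290 under another setting.

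Signs turned for values that had not passed, the cause not tested. DNMT1 in THP1 was -0.013 after centring and from -0.083 to 0.096 on leaving out 1 array. DNMT1 for NOMO1 against MV411 was -0.0096 after quantile normalization and from -0.10 to 0.13 on leaving out 1 array. DNMT3A with the mean of its probe sets was 0.20 for NOMO1 against THP1 and -0.033 for THP1 against MV411. DNMT3B in NOMO1 was 0.050 after quantile normalization and from -0.10 to 0.056 on leaving out 1 array, and for THP1 against MV411 from -0.12 to 0.20. UHRF1 with GSK3510477 ran from -0.048 to 0.11 on leaving out 1 array. Of called values, TAPBP between GSK3484862 and DAC was -0.033 with the mean of its probe sets, and the germline list between GSK3484862 and DAC turned direction under the dim filter (adjusted p = 0.628).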

Other observations

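The count without genes at the floor on all arrays was added after the first count had been seen. Of 6418 genes at the floor in MV411 DMSO, 44 were at least 2-fold higher with GSK3484862. Of these 44, 11 (25%) lay at least 2-fold above the floor in THP1 or NOMO1 DMSO, against 418 (6.56%) of the 6374 others (odds ratio 4.75, Fisher's exact test, two-sided p = 0.000107). This comparison decides nothing, because 4294 of the others lay at the floor on all 16 arrays and could not have lain above it. Without them it was 418 of 2080 (20.1%), with an odds ratio of 1.33 (Fisher's exact test, two-sided p = 0.447), a count that errs the other way since the rest were detected in another group by construction. Whether the raised genes were expressed in the other lines more often stays open.

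Further lists passed in THP1 and NOMO1. In THP1, 4 of 23 protocadherin cluster genes rose and 0 fell, including PCDHB11 (1.49 ± 0.19), with adjusted p = 0.00168, and adjusted p = 0.111 with an estimated correlation. In NOMO1 11 of 42 NF-kB and inflammatory cytokine genes rose and 0 fell, including CXCL1 (1.93 ± 0.16), with adjusted p = 9.3e-05, and adjusted p = 0.367 with an estimated correlation. CDKN1C, an imprinted cell cycle inhibitor, rose in MV411 (2.73 ± 0.17), THP1 (1.29 ± 0.17) and NOMO1 (0.98 ± 0.17).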
